A study of Mus musculus with 12 samples.

How the data were processed

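Polyadenylated RNA was sequenced in stranded libraries from NMRI mice. Neocortex tissue was taken at postnatal day 10 (P10) and postnatal day 49 (P49). Cultures were dissociated neocortical cells from embryonic day 16.5, kept for 14 days and then left untreated (control), given DRB for 2 hours at 50 uM, or, in a second experiment, given DRB with or without bicuculline for 1 hour at 20 uM. DRB blocks transcription elongation by RNA polymerase II, and bicuculline blocks GABA-A receptors and so raises network activity. Each of the 6 groups has 2 libraries, 12 in all.

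The authors aligned the reads with STAR 2.4.0f1 to mm10 (GRCm38), per the labels; how the reads were then counted and filtered is not given in the sources used here. The 2 deposited tables list junctions with whole numbers per library. Per the file headers, the values used here are counts of reads across each exon-exon junction, as deposited, with no normalisation. One table holds 8 libraries (P10, P49, control and the first DRB group) and 638144 rows, the other 4 libraries (the second DRB group and DRB with bicuculline) and 449433 rows. The header of each table has 3 more names than its rows have cells (67 against 64 and 39 against 36), so the junction columns were read by number after this shift.

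Column names show a group but carry no replicate number of the labels, so each group was given as many junction columns as it has libraries, and libraries have no identity beyond their group. Letters (a and b) at the end of names in the second table match no replicate number in the labels and entered an alternative only. The numbers 1 and 2 used for libraries follow the column order only. Names mark the P10, first DRB and bicuculline columns. The control, P49 and second DRB columns were assigned by elimination. A further 72 columns of per-library values, which give other measures at each intron, could not be given to a library and were not used in any step of what is reported. Intron retention, which needs those columns, is not reported here. Whether cultures of the first DRB group also received TTX, a blocker of action potentials that some column names mention, is not given in the sources used here. Both P10 columns carry the same tissue code. Neither is it stated whether the libraries of a group came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

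Junctions were matched to the introns of GENCODE mouse annotation (release number 21), which held 99.1% to 99.3% of spliced reads. That gave 195701 annotated introns in the first table and 183624 in the second. Each distinct junction was counted once and summed per gene symbol (19404 and 18139 genes), so a read across several junctions counts once for each. Genes with 1 exon have no spliced reads and were not measured. How reads that map to several places were treated is not given, so values of genes with near-identical copies, such as Tuba1a, Tubb2b, Hnrnpa1, Hnrnpa3 and Ly6c1, are uncertain. Reads carry no molecular identifiers.

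Gene sums were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, two-sided) after its filter on low counts. They are given as CPM, counts scaled to the library size as adjusted by TMM. The first table was fitted with all 8 libraries, which share an estimate of the spread, and the second with its 4. Benjamini-Hochberg adjusted p-values (adjusted p) were called at 0.05. Lists of genes were tested with camera in limma 3.58.1 (preset correlation 0.01, and again with an estimated correlation), adjusted over the 16 lists. The overlap of calls was tested with Fisher's exact test over genes tested in both experiments, adjusted over 8 tests. With 2 libraries per group, label permutations were not used. The comparisons, tests, thresholds, lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule named the 5 largest log2 changes per direction among called genes with a mean log2 CPM of at least 3 over the libraries of the table, and up to 4 members per list by p.

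Alternatives were DESeq2 1.42.0 with its size factors, no filter on low counts, only the groups compared in the fit, each library left out in turn, every junction with a gene symbol and, in the second table, a block on the letter in the column names. The models were tested on simulated counts with 200 changed genes per comparison and a set dispersion of 0.02, so the shares recovered hold for that spread. The test recovered 92% of genes changed 2-fold for P49 against P10 (15070 genes), 82% for DRB against control (14874) and 84% for bicuculline against DRB (14235). At a 1.5-fold change it recovered 21%, 20% and 22%, and false calls numbered 5, 0 and 5. Smaller changes than this were called in the data, such as Nr4a3 with bicuculline at a log2 change of 0.33 ± 0.051 (SE). The shares recovered thus do not give the share of changes missed here. Computation used R 4.3.3.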

Results

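Spliced reads of 12 mouse libraries were compared, 2 from each of 6 groups: neocortex of postnatal day 10 (P10) and postnatal day 49 (P49), untreated neocortical cultures (control), cultures given DRB, and, from a second experiment, cultures given DRB alone or DRB with bicuculline. A read counted when it crossed an exon-exon junction of an annotated intron, and reads from retained introns were not counted. Libraries held 49559425 to 73900724 spliced reads in the first table and 62423801 to 69852903 in the second. Values are counts scaled to TMM-adjusted library size (CPM), given as mean ± SD with n = 2 throughout. Changes were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p), and "rose" and "fell" are used for genes that passed at 0.05.

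Adult and developing neocortex were compared first, to ask how the transcripts of neurons and glia change with age. Markers of growing neurons fell. Dpysl3, which acts in axon growth, fell from 787 ± 72 CPM at P10 to 45.9 ± 4.0 at P49, a log2 change of -4.10 ± 0.075 (SE; adjusted p = 3.7e-11). Its relative Dpysl5 fell from 377 ± 29 to 27.4 ± 3.0 CPM, the tubulin Tubb2b from 620 ± 60 to 63.7 ± 0.99, Marcksl1 from 118 ± 0.37 to 14.7 ± 0.25 and Dcx, a microtubule protein of migrating neurons, from 30.2 ± 0.76 to 5.87 ± 0.25. Myelin transcripts rose: Mal from 5.06 ± 0.49 to 64.5 ± 2.5 CPM, Opalin from 2.81 ± 0.40 to 29.7 ± 0.89, Mobp from 67.0 ± 6.7 to 303 ± 4.9 and Mog from 23.1 ± 1.5 to 84.1 ± 6.9. Pvalb, a calcium buffer of fast-spiking interneurons, rose from 5.08 ± 1.8 to 74.2 ± 6.4 CPM (log2 change 3.87 ± 0.21, SE; adjusted p = 4.9e-08).

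Of 15058 genes tested, 4315 were higher at P49 and 4414 lower, 971 and 1061 of them by 2-fold or more. Both P10 columns carry the same tissue code, so the P10 libraries may come from 1 animal. These counts may then hold differences between animals as well as age. Among genes with a mean log2 CPM of at least 3 over the first table, the largest increases were in Igfn1 (0.786 ± 0.21 to 39.6 ± 4.4 CPM), Xdh, xanthine dehydrogenase (1.17 ± 0.13 to 32.6 ± 0.35), the heat shock factor Hsf4 (1.47 ± 0.12 to 32.2 ± 1.7), Igfbp6 (2.87 ± 0.046 to 44.9 ± 3.7) and Pvalb. The largest decreases were in Trpa1, a cation channel (21.5 ± 1.9 to 0.588 ± 0.027 CPM), Dpysl3, the surface protein Cd24a (13.9 ± 0.097 to 0.859 ± 0.050), Trim67 (19.3 ± 1.2 to 1.31 ± 0.11) and Dpysl5.

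Activity genes were higher in the adult. Of 16 immediate early genes, which neuronal activity induces without new protein, 12 rose and 2 fell. The list passed camera (adjusted p = 0.0016; adjusted p = 0.13 with an estimated correlation). Here and below, the second value does not measure the effect of correlation alone. The estimate for this list was -0.021, below the preset 0.01, yet the unadjusted camera p went from 2.0e-04 to 0.016. Arc, a regulator of synaptic strength, rose from 7.01 ± 0.027 to 77.4 ± 7.6 CPM, Fos, a subunit of the AP-1 transcription factor, from 6.73 ± 0.62 to 46.0 ± 0.78, the nuclear receptor Nr4a1 from 30.5 ± 1.5 to 113 ± 3.7 and the phosphatase Dusp1 from 6.86 ± 0.47 to 32.4 ± 0.86. Nr4a3, related to Nr4a1, fell from 18.4 ± 1.2 to 8.83 ± 0.34 CPM, and Fosl2 fell too (6.36 ± 0.57 to 5.09 ± 0.089; chosen after its values were seen, as was Nr4a3). Of 13 late activity genes 10 rose and 1 fell (camera, adjusted p = 0.0082; adjusted p = 0.196 with an estimated correlation), among them the synaptic protein Nrn1 (36.2 ± 4.0 to 103 ± 0.27 CPM) and the cyclooxygenase Ptgs2 (1.65 ± 0.059 to 11.4 ± 1.2). Rheb, chosen after its values were seen, was the late gene that fell (256 ± 8.9 to 231 ± 3.1).

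Neuronal lists moved in part. All 12 immature neuron genes fell (camera, adjusted p = 8.7e-08; adjusted p = 0.13 with an estimated correlation). Voltage-gated channels had 13 of 20 higher and 4 lower (0.019; adjusted p = 0.529 with an estimated correlation), with the potassium channel Kcnc1 at 29.1 ± 3.8 against 5.92 ± 0.19 CPM and the calcium channel Cacna1g lower, at 207 ± 5.6 against 353 ± 13. Presynaptic genes had 12 of 20 higher and 5 lower (0.034; adjusted p = 0.63 with an estimated correlation). Snap25, a SNARE protein of vesicle fusion, rose from 1007 ± 22 to 2991 ± 53 CPM, and the adhesion molecule Nrxn2 fell from 615 ± 13 to 378 ± 1.6. Postsynaptic genes, with 8 of 19 higher and 5 lower, did not pass (0.59), although the kinase Camk2a rose from 1668 ± 30 to 3694 ± 2.8 CPM and the scaffold Dlg2 fell from 438 ± 0.47 to 276 ± 4.7. Interneuron markers, with 5 of 10 higher and 3 lower, did not pass either (0.37). Gad1, which makes GABA, rose from 227 ± 20 to 499 ± 25 CPM, and Reln, a secreted guidance protein, fell from 328 ± 4.8 to 199 ± 3.2.

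Of the splicing lists, SR and hnRNP proteins had more members lower at P49 than higher, and the other lists had more higher. SR proteins, which promote exon recognition, had 1 of 13 higher and 8 lower (camera, adjusted p = 0.026; adjusted p = 0.436 with an estimated correlation), such as Srsf3 (51.5 ± 2.0 to 36.0 ± 1.1 CPM), Srsf6 (105 ± 0.088 to 78.0 ± 1.2) and Tra2b (58.2 ± 2.9 to 41.5 ± 0.81). Tra2a fell from 96.3 ± 6.5 to 70.3 ± 1.4 CPM and lost its call when every junction with a gene symbol was counted (adjusted p = 0.114; 3.6e-11 to 0.114 over the alternatives). hnRNP proteins had 3 of 19 higher and 13 lower (0.034; adjusted p = 0.515 with an estimated correlation). Hnrnpab was at 105 ± 3.1 against 146 ± 8.7 CPM, Ptbp1, a splicing repressor, at 38.3 ± 1.7 against 51.4 ± 2.0, and Hnrnph2 higher, at 51.4 ± 4.9 against 32.2 ± 1.4. CLK and SR protein kinases, which phosphorylate SR proteins, had 3 of 9 higher and 1 lower and did not pass (0.44). Srpk3 rose from 4.57 ± 0.36 to 11.5 ± 0.39 CPM, Clk4 rose from 84.6 ± 0.90 to 108 ± 6.8 and Srpk1 fell from 149 ± 4.7 to 117 ± 3.8. Other splicing-associated factors had 10 of 26 higher and 5 lower (0.71). Ogt, a sugar transferase, rose from 322 ± 6.1 to 473 ± 1.9 CPM. Sfpq fell from 388 ± 2.3 to 251 ± 2.5 CPM, its partner Nono from 190 ± 4.5 to 133 ± 1.8, and the cold-inducible Rbm3 from 73.9 ± 5.5 to 49.1 ± 1.3.

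Among glia, oligodendrocyte and myelin markers had 11 of 13 higher and 1 lower (camera, adjusted p = 0.0017; adjusted p = 0.515 with an estimated correlation). Their precursor markers had 0 higher and 4 of 5 lower (0.019; adjusted p = 0.196 with an estimated correlation), with Gpr17 from 15.2 ± 0.61 to 4.48 ± 0.36 CPM and Pdgfra from 111 ± 3.4 to 65.4 ± 0.98. Astrocyte markers, with 4 of 9 higher and 3 lower (0.69), microglia markers, with 1 of 10 in each direction (0.93), and endothelial and mural markers, with 3 of 9 higher and 4 lower (0.97), did not pass. Kdr, a receptor of growing vessels, fell from 95 ± 0.073 to 24.2 ± 0.89 CPM, and the glucose transporter Slc2a1 rose from 58.1 ± 2.2 to 126 ± 13. Counts adjusted over the list alone equalled these, except for 14 hnRNP proteins lower, 7 postsynaptic genes lower and 6 interneuron markers higher. For postsynaptic genes the median log2 change was -0.07 and the mean 0.18, and for endothelial and mural markers -0.13 and -0.05, while camera pointed up for both.

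**Figure D1:**
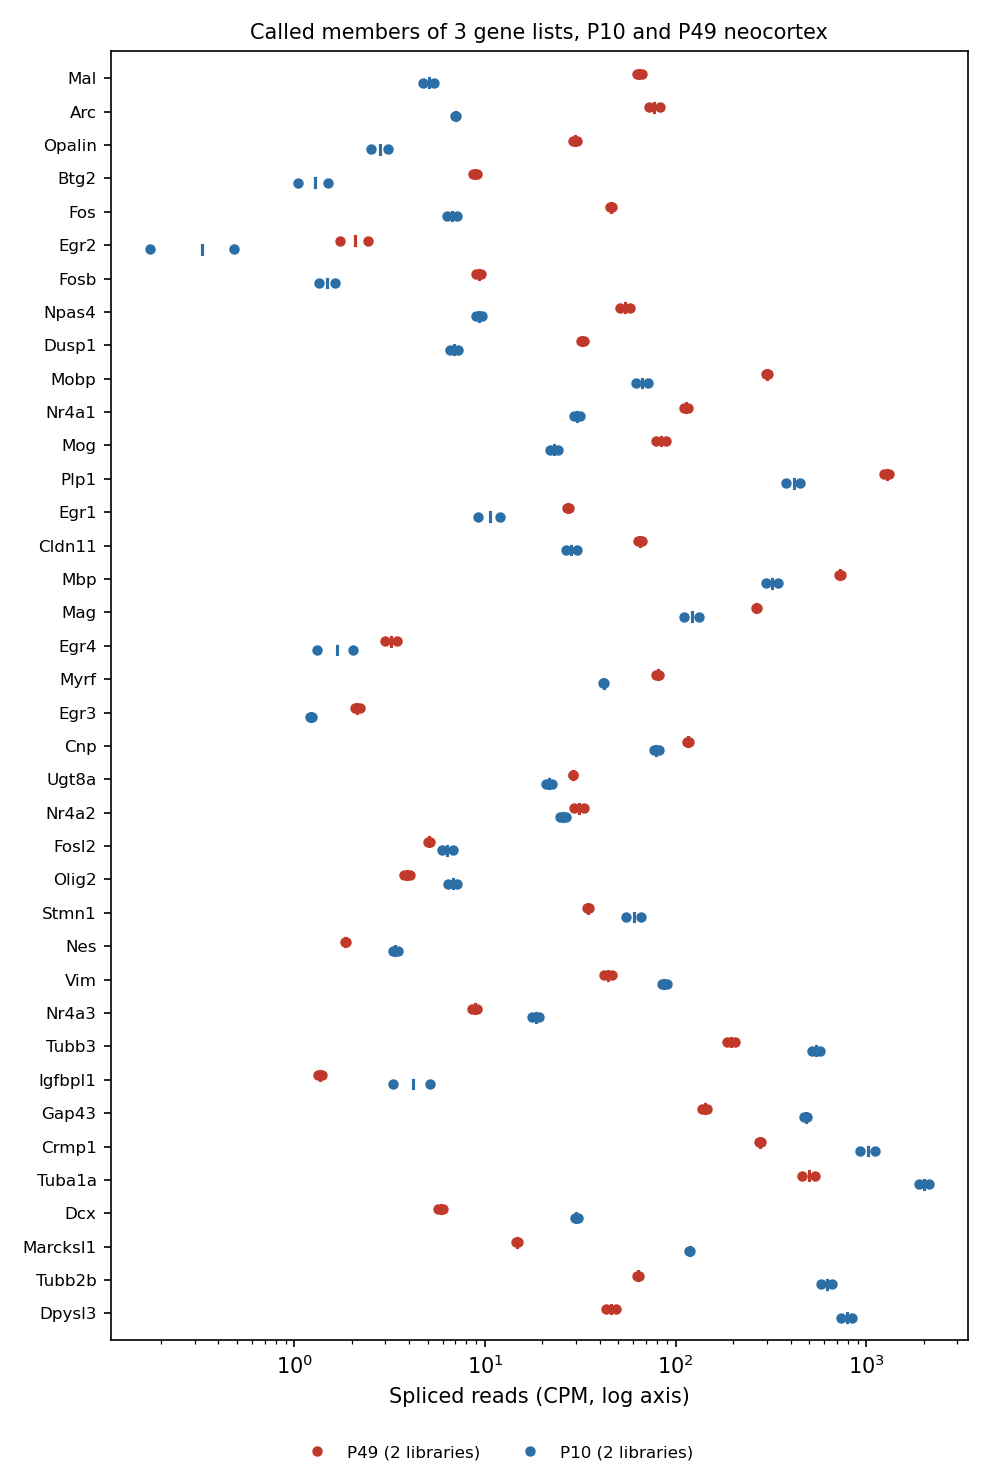
Spliced reads in CPM (x axis, log scale) of the called members of the immediate early, oligodendrocyte and immature neuron lists, with a point for each of the 2 P10 and 2 P49 libraries and a line at each mean. Most immediate early and myelin genes are higher at P49, such as Arc with means of 7.01 and 77.4 CPM, and immature neuron genes are lower, such as Dcx with 30.2 and 5.87 CPM.

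Cultures were given DRB for 2 hours, which blocks transcription, to ask which transcripts outlast the block. CPM are relative values scaled by TMM, and total RNA was not measured here, so a rise under DRB is relative to other genes. A larger share means a rise in these values. Transcripts of Id3, an inhibitor of helix-loop-helix factors, fell from 24.9 ± 0.66 CPM in control cultures to 1.45 ± 0.30 under DRB, a log2 change of -4.11 ± 0.16 (SE; adjusted p = 2.3e-08). Sox9, an astrocyte transcription factor, fell from 39.3 ± 2.8 to 4.69 ± 0.58 CPM, and Thbs1, the secreted thrombospondin, from 708 ± 60 to 91.5 ± 1.3. Synaptic transcripts took a larger share: Syt1, the calcium sensor of vesicle release, rose from 338 ± 1.2 to 692 ± 18 CPM and Camk2a from 390 ± 11 to 807 ± 11. The immediate early gene Nr4a1 rose from 14.2 ± 0.20 to 84.7 ± 0.48 CPM (log2 change 2.58 ± 0.059, SE; adjusted p = 1.9e-09).

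Of 14405 genes tested, 4658 were higher under DRB and 5037 lower, 429 and 1706 of them by 2-fold or more. Among genes with a mean log2 CPM of at least 3 over the first table, tissue included, the largest increases were in Nr4a1, Crhbp, which binds corticotropin-releasing hormone (1.59 ± 0.28 to 6.99 ± 1.4 CPM), Sst, the peptide somatostatin (12.2 ± 0.46 to 49.1 ± 0.88), Igfn1 (0.0957 ± 0.030 to 0.370 ± 0.020) and Fos (12.4 ± 0.22 to 43.4 ± 3.5). Igfn1 reached that minimum through P49 neocortex and had few reads in culture. Fosb, under the minimum, rose more (log2 change 3.36). The largest decreases were in Id3, Ajuba, an adaptor of cell junctions (32.9 ± 1.7 to 3.56 ± 0.088 CPM), the secreted Wisp2 (46.8 ± 5.0 to 5.36 ± 1.1), Sox9 and Thbs1.

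All 20 presynaptic genes rose (camera, adjusted p = 1.4e-08; adjusted p = 0.376 with an estimated correlation). Among them was Snap25 (326 ± 20 to 700 ± 12 CPM). Of 19 postsynaptic genes 18 rose (1.4e-07; adjusted p = 0.376 with an estimated correlation), including the receptor subunit Grin1 (387 ± 21 to 811 ± 7.1). Channels had 17 of 20 higher (4.4e-05; adjusted p = 0.389 with an estimated correlation), and interneuron markers 9 of 10 (0.0012; adjusted p = 0.315 with an estimated correlation), such as the peptide Npy (22.1 ± 1.9 to 63.5 ± 4.4). Of these lists, 0 members were called lower by edgeR, with 1 channel lower at an unadjusted p under 0.05 and also when adjusted over the list alone. Immature neuron genes had 8 of 12 higher and 3 lower and did not pass (0.10). Gap43, a growth cone protein, rose from 230 ± 3.2 to 558 ± 42 CPM, while the filament proteins Nes and Vim fell, from 53.9 ± 6.3 to 17.0 ± 0.96 and from 3447 ± 234 to 1727 ± 26.

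Activity genes split under DRB. Whether these DRB cultures also received TTX, which blocks action potentials, is not given, so these changes cannot be credited to DRB alone. Immediate early genes had 8 of 17 higher and 4 lower (camera, adjusted p = 0.174). Fosb rose from 1.05 ± 0.33 to 10.9 ± 1.3 CPM, and Dusp1 fell from 18.6 ± 0.38 to 5.0 ± 0.92. The others that fell were Klf4, Atf3 and Btg2, chosen after their values were seen. Late activity genes had 9 of 13 higher and 3 lower (0.114), with the secreted Scg2 at 60.5 ± 4.9 against 27.5 ± 1.0 CPM and the kinase Plk2 at 55.0 ± 4.3 against 127 ± 0.75.

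The splicing lists did not pass. CLK and SR protein kinases had 2 of 9 higher and 4 lower (camera, adjusted p = 0.541), with Clk1 falling from 198 ± 5.5 to 119 ± 7.1 CPM, a log2 change of -0.73, and Srpk2 rising from 205 ± 0.37 to 260 ± 1.3. SR proteins had 3 of 13 higher and 7 lower (0.546), with Srsf7 from 102 ± 3.4 to 59.8 ± 0.77. hnRNP proteins had 5 of 19 higher and 3 lower (0.598). Ptbp1 fell from 141 ± 0.83 to 60.1 ± 1.9 CPM and its neuronal relative Ptbp2 rose from 133 ± 1.0 to 173 ± 3.7. Other splicing-associated factors had 9 of 26 higher and 3 lower (0.174), with the RNA helicase Ddx39b rising from 475 ± 11 to 576 ± 1.8.

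Glial and vascular lists did not pass either. Astrocyte markers had 2 of 9 higher and 4 lower (camera, adjusted p = 0.534), oligodendrocyte and myelin markers 6 of 12 higher and 3 lower (0.534), and their precursor markers 0 higher and 2 of 3 lower (0.174). The myelin protein Mbp rose from 19.9 ± 2.7 to 39.2 ± 4.2 CPM, and the transcription factors Olig2 and Sox10 fell, from 11.4 ± 1.0 to 4.89 ± 0.16 and from 3.78 ± 0.92 to 1.06 ± 0.32. Microglia markers had 1 of 8 in each direction (0.795), with Aif1 rising from 12.8 ± 0.92 to 23.3 ± 0.29. Endothelial and mural markers had 2 of 8 higher and 5 lower (0.183), with the smooth muscle actin Acta2 from 545 ± 85 to 128 ± 2.0 CPM and Kdr from 100 ± 12 to 24.3 ± 1.8. Counts adjusted over the list alone equalled those given, except for the channels. For hnRNP proteins the median log2 change was 0.07 and the mean -0.01, and camera pointed up.

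**Figure D2:**
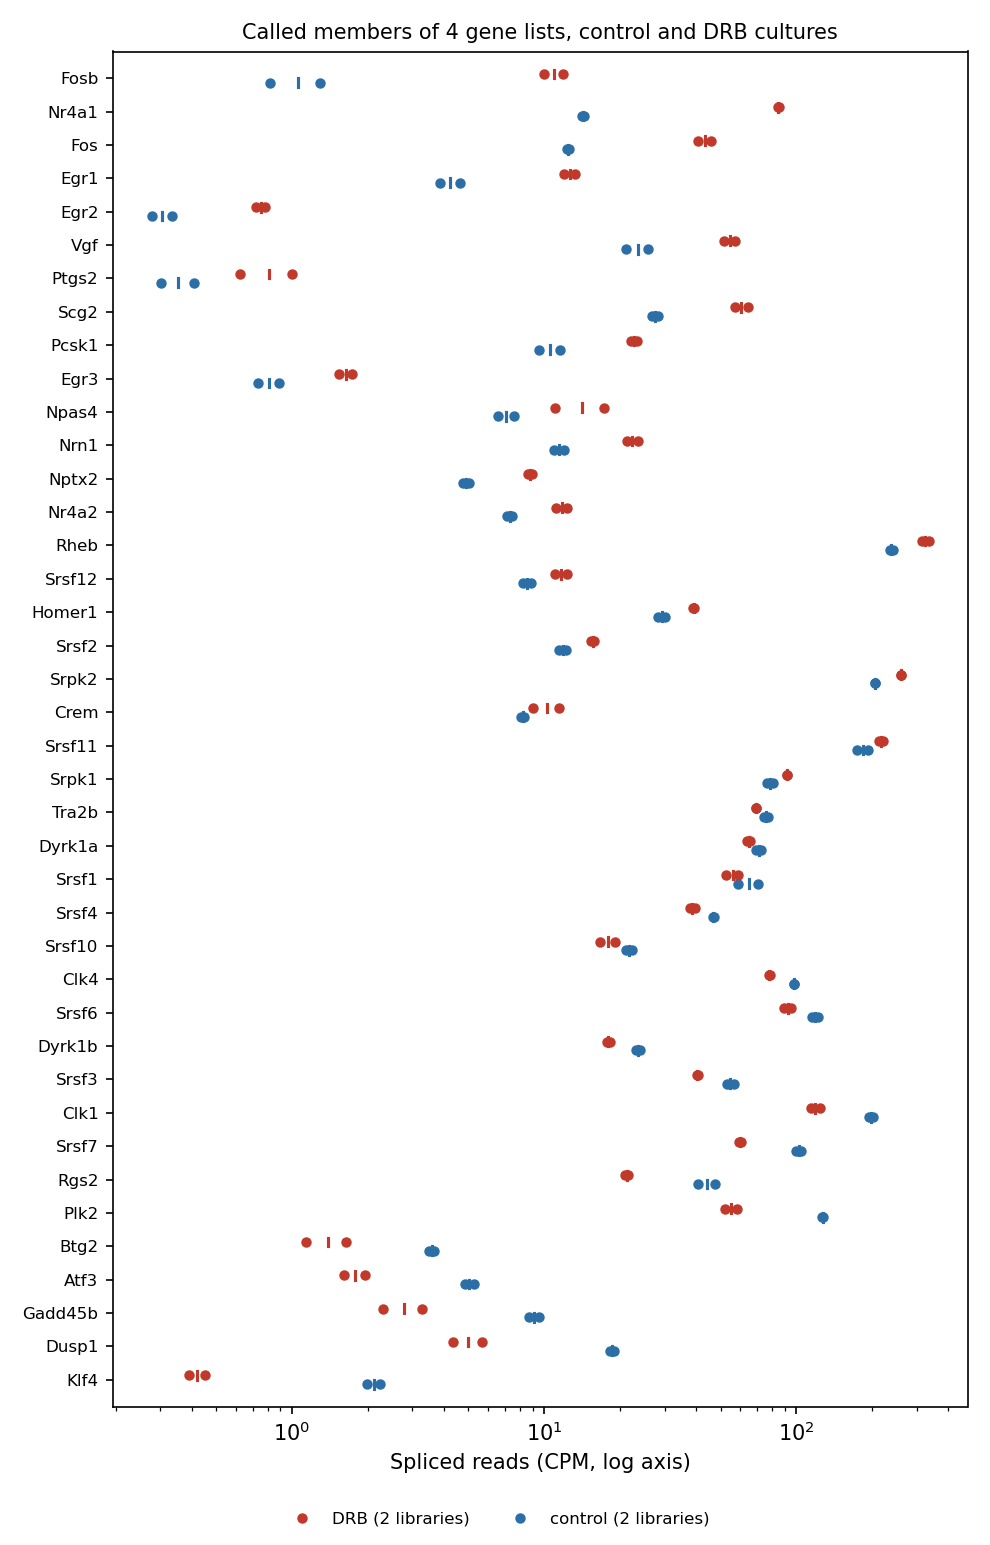
Spliced reads in CPM (x axis, log scale) of the called members of the immediate early, late activity, CLK kinase and SR protein lists, with a point per library (2 control and 2 DRB) and a line at each mean. Activity genes lie on both sides, such as Nr4a1 with means of 14.2 and 84.7 CPM and Dusp1 with 18.6 and 5.0 CPM, and Clk1 is lower under DRB, with 198 and 119 CPM.

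In the second experiment, bicuculline was given for 1 hour with DRB, to ask which transcripts answer to activity under the block. Neither network activity nor the strength of the block was measured here. Npas4, a transcription factor of neuronal activity, rose from 13.7 ± 1.2 CPM with DRB alone to 270 ± 5.6 with bicuculline, a log2 change of 4.30 ± 0.055 (SE; adjusted p = 4.7e-23). Arc rose from 0.980 ± 0.32 to 12.9 ± 1.4 CPM, Fos from 46.6 ± 4.8 to 205 ± 14, Fosb from 9.74 ± 0.92 to 60.7 ± 3.1, Gadd45g, a stress-response gene, from 4.60 ± 0.15 to 24.7 ± 1.4 and Dusp1 from 7.14 ± 1.2 to 28.3 ± 0.29.

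Of 14247 genes tested, edgeR called 26 higher and 4 lower with bicuculline, 15 and 0 of them by 2-fold or more. At an unadjusted p under 0.05 the counts were 310 and 266, and DESeq2 called 24 and 1. With no filter on low counts edgeR called 45 and 22 of 18139 genes. Without bicuculline library 2 edgeR called 40 and 35, without DRB library 1 35 and 13, and without DRB library 2 53 and 29. The genes called lower were Cd36, a fatty acid receptor (35.2 ± 4.3 to 18.8 ± 6.9 CPM), Gpnmb (62.4 ± 7.9 to 42.5 ± 3.8), the macrophage receptor Mrc1 (9.55 ± 0.64 to 6.37 ± 1.1) and Xdh (3.30 ± 0.081 to 1.95 ± 0.17), the last 2 chosen after their values were seen. In DESeq2, Cd36 and Gpnmb lost their calls (adjusted p = 1.00 and 0.18), with log2 changes of -0.91 and -0.56 in both tools. Over the alternatives their adjusted p ranged from 1.6e-53 to 1.00 and from 8.8e-32 to 0.18.

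Of 17 immediate early genes 12 rose, 15 when adjusted over the list alone (camera, adjusted p = 3.6e-29; adjusted p = 0.404 with an estimated correlation). Of 13 late activity genes 4 rose, 7 when adjusted over the list alone (6.3e-07; adjusted p = 0.404 with an estimated correlation). The 4 were Plk2 (66.5 ± 6.0 to 152 ± 5.9 CPM), Rgs2, a regulator of G-protein signalling (42.3 ± 1.8 to 78.2 ± 1.2), Gadd45b (1.94 ± 0.21 to 5.46 ± 0.34) and Ptgs2 (0.947 ± 0.23 to 2.19 ± 0.14). Ptgs2 lost its call without bicuculline library 1 (adjusted p = 0.057; 1.6e-06 to 0.057 over the alternatives). Late genes that did not pass included Scg2, at 63.7 ± 1.6 against 57.3 ± 2.5 CPM.

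Other lists held no called gene in edgeR. DESeq2 added no call among their named members. Oligodendrocyte and myelin markers (12 tested; 1 lower adjusted over the list alone, 3 lower at an unadjusted p under 0.05) and microglia markers (8 tested; 2 lower adjusted over the list alone, 4 at an unadjusted p) were shifted down in camera (adjusted p = 5.6e-04; adjusted p = 0.404 with an estimated correlation, and 0.0042; adjusted p = 0.848 with an estimated correlation). The microglia genes C1qa, C1qb, C1qc and Ctss had no call with all libraries and were called lower without bicuculline library 2 (adjusted p from 0.0020 to 0.043), C1qa also without DRB library 2 (0.016; 0.0042 to 1.00 over the alternatives). CLK and SR protein kinases had 0 of 9 called, with 1 higher adjusted over the list alone. That was Clk1, at 188 ± 0.94 against 168 ± 4.9 CPM (adjusted p = 0.138, and 0.0033 over the list alone), which was called with no filter on low counts (0.018; 7.7e-05 to 0.816 over the alternatives). The mural marker Acta2, at 424 ± 2.0 against 380 ± 59 CPM, was called higher with no filter (adjusted p = 0.0077) and without DRB library 2 (6.5e-07; 5.1e-07 to 1.00 over the alternatives). The lists for SR proteins (13 genes), hnRNP proteins (19), other splicing-associated factors (26), presynaptic genes (20), postsynaptic genes (19), channels (20), interneurons (10), immature neurons (12), astrocytes (9), precursors (3) and endothelial and mural cells (6) had 0 called, 0 adjusted over the list alone and no camera call. At an unadjusted p under 0.05 they held 1 gene, an endothelial and mural marker. For SR proteins (median log2 change -0.015, mean 0.0020) and endothelial and mural markers (-0.0088 and 0.0092) camera pointed down.

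**Figure D3:**
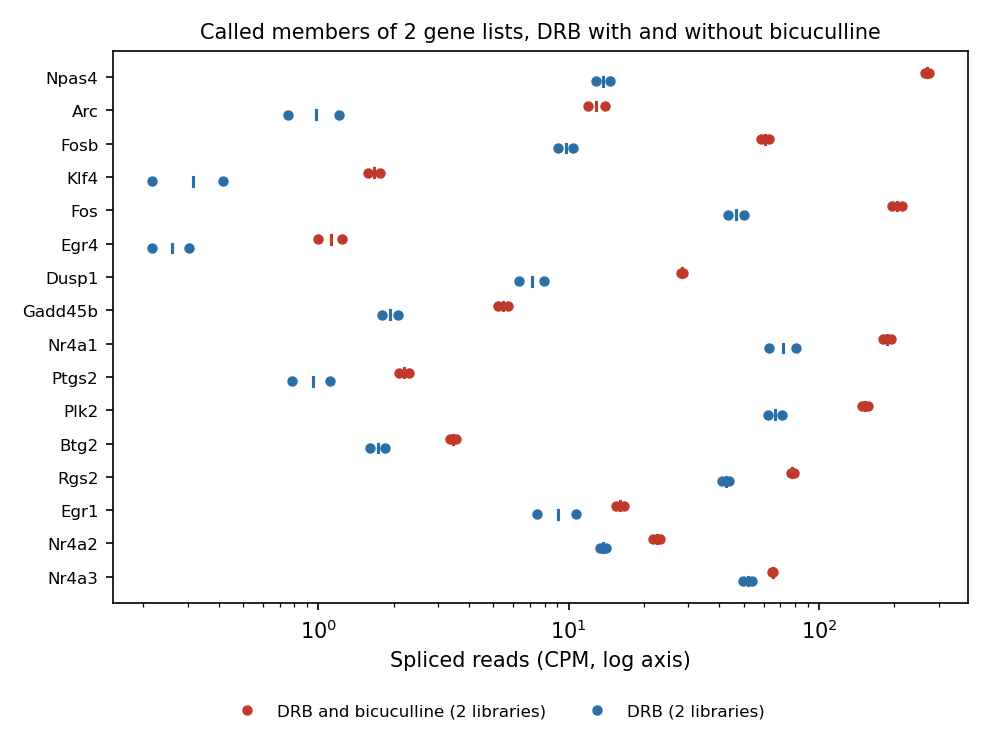
Spliced reads in CPM (x axis, log scale) of the called immediate early and late activity genes, with a point per library (2 with DRB alone, 2 with DRB and bicuculline) and a line at each mean. Each gene drawn is higher with bicuculline, from Npas4 with means of 13.7 and 270 CPM to Nr4a3 with 51.8 and 65.2 CPM.

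**Figure D4:**
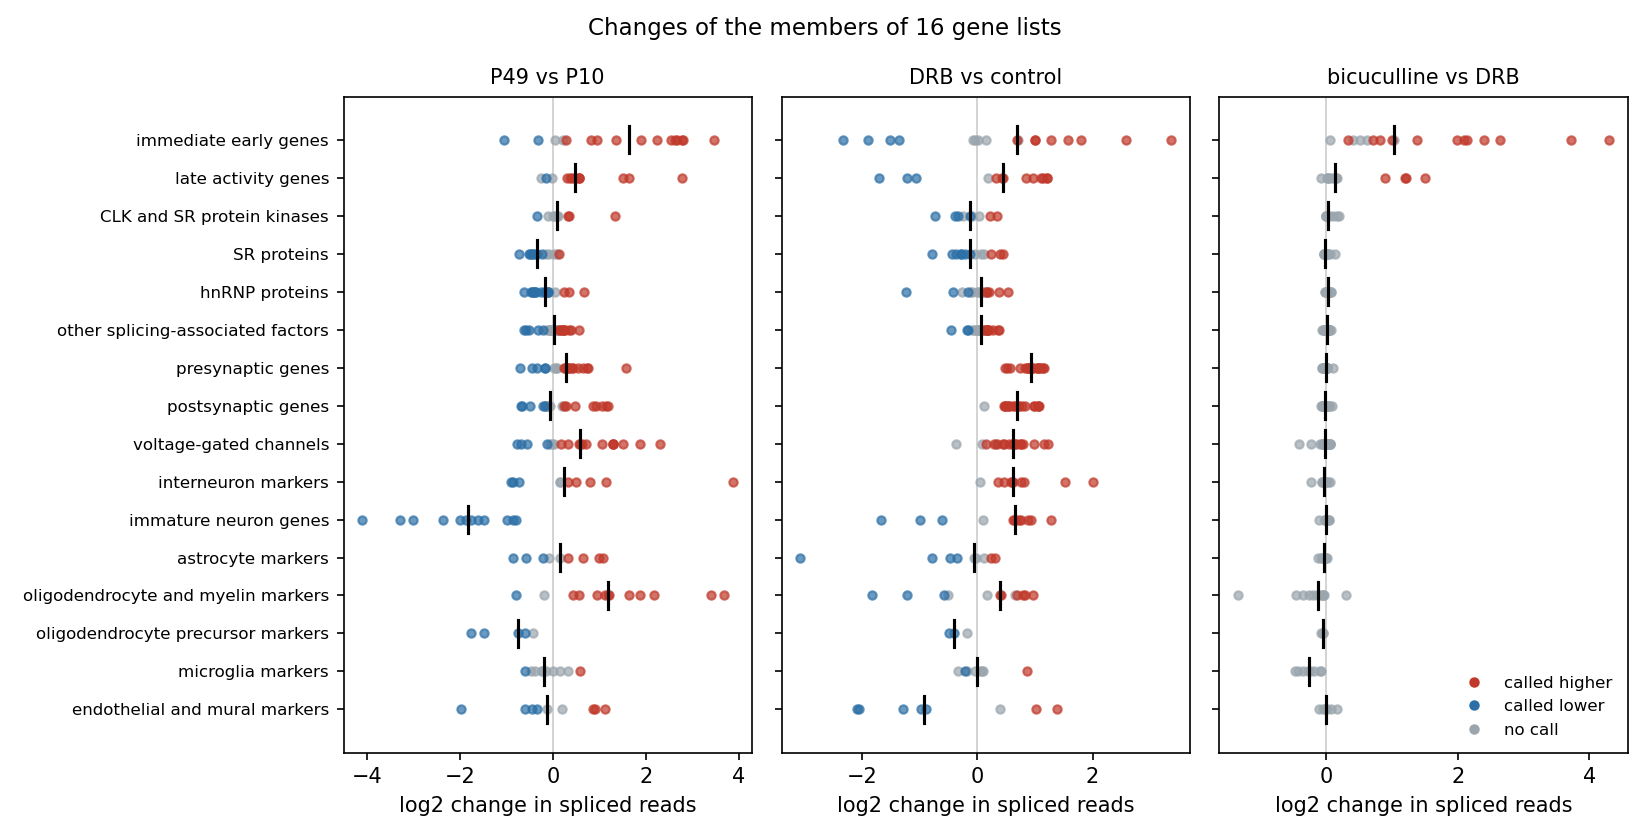
Log2 change in spliced reads (x axis) of each tested gene of the 16 lists in the 3 comparisons, with called genes in colour and a black line at the median of each list. The median of immediate early genes is 1.63 at P49 against P10 and 1.02 with bicuculline, and the presynaptic median is 0.93 under DRB.

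Genes that rose with bicuculline were compared with the calls of the first experiment, which shares no library with the second. This comparison was chosen after the data were seen. Of the 26 genes, 19 were also higher at P49 than at P10, against 7.61 by chance (odds ratio 6.58; Fisher's exact test, two-sided, adjusted p = 3.9e-05, over 13828 genes tested in both). Only 2 were lower at P49, against 7.92 by chance (odds ratio 0.19; adjusted p = 0.038), Nr4a3 and Arl5b. Under DRB in the first experiment, where TTX may also have been present, 14 of the 26 were lower, against 9.12 by chance (odds ratio 2.16; adjusted p = 0.165, over 13908 genes), and 8 were higher, against 8.61 (odds ratio 0.897; adjusted p = 1). With calls at an unadjusted p under 0.05 the odds ratios were 1.36 for P49 higher (adjusted p = 0.037), 0.737 for P49 lower (0.042), 2.07 for DRB lower (2.6e-09) and 0.411 for DRB higher (2.0e-09). Dusp1, Gadd45g, Klf4, Plk2, Rgs2, Gadd45b and Btg2 were among those lower under DRB, and Npas4, Fos, Fosb, Nr4a1 and Egr1 among those higher. Most of the 19 genes higher at P49, such as Npas4, Arc, Fos and Dusp1, belong to the activity lists already reported as higher there. That overlap thus largely repeats the list result, and Fisher's exact test treats genes as independent, which they are not.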

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

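The count of every junction with a gene symbol, the overlap of gene calls and the block on column letters were chosen after seeing the data. Fits without a library leave a lone library in its group, which is assumed to vary like the other groups. Counts of P49 against P10 and of DRB against control stayed within 1.5 times of those reported in every alternative run. Without a library they ranged from 3692 to 4017 higher and 3811 to 4124 lower for P49, and from 4044 to 4129 and 4385 to 4571 for DRB. For named genes, values that kept direction and side of the threshold numbered 285 for P49 against P10, with 2 gained calls and 1 lost, 276 for DRB against control, and 261 for bicuculline against DRB, with 4 gained, 2 lost and 1 reversed. With a library left out these were 285 kept and 3 gained, then 270 kept, 3 gained, 2 lost and 1 reversed, and then 232 kept, 6 gained, 1 lost and 29 reversed. Unless a cause is named, the cause was not tested. Depth limits genes with few reads: with bicuculline, Egr2 (0.821 to 1.67 CPM) had no call at a log2 change of 1.02, while Nr4a3 (51.8 to 65.2 CPM) was called at 0.33.

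For bicuculline against DRB, DESeq2 gave 1 lower, and no filter on low counts, with more genes tested, 45 higher and 22 lower. Without a library, higher ranged from 27 to 53 and lower from 5 to 35. With an estimated correlation, 0 lists passed camera in each of the 3 comparisons, against 9, 4 and 4. The size of the correlation is not the only difference between these runs. For late activity genes with bicuculline the estimate was 0.0115, near the preset 0.01, yet the unadjusted camera p went from 7.9e-08 to 0.033. With an estimated correlation, camera also takes its degrees of freedom from the few libraries, not from the genes. The loss of all lists therefore does not measure the effect of correlation alone. At an unadjusted p, with more genes in each set, the overlap of bicuculline higher with DRB higher had an odds ratio of 0.411 and with DRB lower of 2.07, both past the threshold, and that of bicuculline lower with DRB lower was 1.02, against 0.617. The overlap of bicuculline higher with P49 higher was 1.36 and with P49 lower 0.737, weaker than the 6.58 and 0.19 reported but past the threshold. In the first table no paired analysis was possible because its column names carry no replicate number. In the second, a replicate block on the letters a and b gave 61 higher and 37 lower for bicuculline against DRB, and Clk1 (log2 change 0.17, adjusted p = 7.7e-05) and Acta2 (0.17, adjusted p = 5.1e-07) gained a call in edgeR, while no other named gene changed its call. These letters match no replicate number in the labels, and what they mark is not given. Deviations of libraries with the same letter had a correlation of 0.227 over 8929 genes, which are not independent. The alternatives for intron retention, its gene lists and its overlap between experiments were not run, since the columns they need were not used.

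Log2 changes that reversed were near 0 in most, and 1 of them, Tra2a with bicuculline, did so in every junction with a gene symbol (0.16). With a library left out, Cx3cr1 under DRB ranged from -0.76 to 0.27. With bicuculline, the lowest and highest were -0.00063 and 0.074 for Clk3, -0.36 and 0.81 for Srpk3, -0.063 and 0.0028 for Srsf5, -0.083 and 0.017 for Tra2a, -0.025 and 0.19 for Hnrnpa1, -0.0085 and 0.076 for Hnrnph3, -0.11 and 0.015 for U2af2, -0.13 and 0.00050 for Slc17a7, -0.044 and 0.23 for Slc17a6, -0.086 and 0.013 for Syt1, -0.15 and 0.0095 for Grin2b, -0.16 and 0.052 for Gria3, -0.093 and 0.016 for Gad1, -0.14 and 0.0093 for Npy, -0.026 and 0.11 for Vim, -0.044 and 0.14 for Nes, -0.067 and 0.028 for Dpysl3, -0.16 and 0.0083 for Gfap, -0.10 and 0.022 for Slc1a2, -0.13 and 0.037 for Pdgfra, -0.17 and 0.033 for Vcan, -0.26 and 0.19 for Cspg4, -0.21 and 0.0067 for Pecam1 and -0.13 and 0.099 for Pdgfrb.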

Other observations

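Of the tests in this part, those for a loss of cells other than neurons and for a larger share of mature neurons were chosen after the result was seen. Each interval is a 95% interval from 1000 draws of genes and holds no spread between libraries.

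With bicuculline 12 of 17 immediate early genes rose although DRB was present in both groups, and the median log2 change of all 17 was 1.02. A weaker block of transcription in the bicuculline cultures would raise the transcripts that DRB lowers most. The 1567 genes lower by 2-fold or more under DRB in the other experiment, activity lists left out, had a median log2 change of 0.018 with bicuculline (value 0.0182, interval 0.0102 to 0.0246), which argues against it as the cause of a change of that size. A slight difference stays open, since this interval lies on the side that a weaker block predicts. Genes higher with bicuculline at an unadjusted p also overlapped with genes lower under DRB (odds ratio 2.07). Transcription in spite of DRB, or slower decay of these transcripts with activity, may account for the pattern and were not tested. Slower decay alone could keep a transcript but not add to it. Most called immediate early genes lay above untreated cultures of the other experiment. Npas4 was at 270 against 7.08 CPM, Fos at 205 against 12.4 and Arc at 12.9 against 1.56. That argues against slower decay alone for them, although the experiments were scaled apart. Klf4 and Btg2 did not lie above (1.67 and 3.44 against 2.11 and 3.58 CPM). Only spliced reads were counted, and intron retention is not reported here. A rise in spliced reads therefore need not be a rise in all transcripts of a gene.

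Synaptic transcripts took a larger share under DRB, with a median log2 change of 0.86. Polymerases already past the blocked step could finish long genes, but synaptic genes exceeded other genes of the same length by a median of 0.84 (value 0.839, interval 0.585 to 0.969; 39 genes with 50 matched genes each), which argues against it. Length and change had a correlation of 0.037 over 13673 genes, which are not independent. A loss of cells other than neurons cannot be told apart from slow decay of neuronal transcripts, which was not tested: oligodendrocyte and myelin markers had a median change of 0.40 (value 0.400), but the interval, -0.540 to 0.749 over 12 genes, includes a loss. Several of those 12 had few reads in control cultures, such as Mog, Mal and Cldn11 (0.39, 1.2 and 1.7 CPM). Other cell lists moved apart, with medians of -0.93 for endothelial and mural markers (5 of 8 lower, 2 higher) and -0.40 for oligodendrocyte precursor markers. The medians were -0.056 for astrocyte markers (4 of 9 lower, 2 higher) and 0.0051 for microglia markers. Abundant astrocyte markers differed under DRB. Slc1a3 (990 to 979 CPM) and Glul (912 to 993) had no call, Aldoc (357 to 424) and Slc1a2 (119 to 147) rose, and Aldh1l1 (316 to 249) and Gfap (187 to 135) fell. In control cultures the vascular markers Pecam1, Flt1, Tek and Rgs5 had few reads (0.84, 1.2, 0.18 and 0.086 CPM), and Pecam1 and Rgs5 rose. The median of that list thus says little about a loss of vascular cells.

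At P49 against P10, 12 of 16 immediate early genes rose and 2 fell, and the median log2 change of all 16 was 1.63. A larger share of RNA from mature neurons at P49 may add to this, and cannot be excluded. The median exceeded that of presynaptic and postsynaptic genes (0.23) by 1.40, with an interval of 0.213 to 2.50 over 16 genes. That interval lies above 0 but is too wide to decide by the margin set for this test. It comes from draws of genes and holds no spread between libraries, so it does not exclude an equal change. Age itself, and recent activity of the animals before tissue was taken, were not tested and stay open.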
